A study of Mus musculus with 6 samples.

How the data were processed

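RNA sequencing was carried out on a mouse ovarian cancer cell line called TKO (triple knockout) and on MNRR1-knockout (KO) cells of the same line. MNRR1 is the protein encoded by the gene Chchd2, which acts in mitochondria at cytochrome c oxidase and in the nucleus as a regulator of transcription. There were 3 KO and 3 wild-type (WT) libraries, where WT means the TKO line with MNRR1 intact. Per the labels, total RNA was isolated with a Qiagen column kit and 1.3 ug of it was made into libraries with the NEBNext Ultra II RNA kit. The descriptions give the KO libraries a single clone name, so they come from 1 clone. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

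The deposited values were raw counts of reads per Ensembl gene, whole numbers with no normalization. Per the submitters' processing notes, the tools included bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2 and DESeq2, and the genome build was GRCm38 (mm10). The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as processed pseudogenes, can therefore be assigned to the wrong gene. Counts per gene cover all exons together, so the loss of a single exon or a small frameshift can leave a gene's count unchanged.

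The count table held 49315 genes, of which 19952 had no count in any of the 6 libraries. Gene symbols, coordinates, GC content and exon lengths came from the GENCODE M21 annotation of GRCm38, to which 49056 gene IDs matched and 259 did not. Total counts ran from 33226463 to 40983999 per library. A count of 0 allows up to 3 counts at the 95% level, which is between 0.0732 and 0.0903 CPM (a gene's count scaled to the library total) in a single library. Floors and intervals of this kind cover counting error only.

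Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its minimum count of 10, which left 16033 genes. Libraries were scaled by the trimmed mean of M values (TMM), and the scaling factors were 1.05, 1.02 and 1.06 for KO replicates 1 to 3 and 0.948, 0.960 and 0.969 for WT replicates 1 to 3. A quasi-likelihood model with robust dispersions and genotype as its only term was fitted to the 6 libraries, and p-values were adjusted by the Benjamini-Hochberg (BH) method over the genes tested. A gene was called higher or lower at an adjusted p under 0.05. Levels are TMM-scaled CPM, given as mean ± SD over 3 replicates, and fold changes are fitted log2 ratios of KO over WT.

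On simulated counts for these 16033 genes, with 50 genes changed at each size, the edgeR test recovered 24% of the genes changed 1.2-fold, 64% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 4-fold. Of its calls, 3.47% were genes that had not been changed. The corresponding share was 6.34% for limma voom and 9.94% for DESeq2. In this simulation 200 genes were changed, whereas 55.7% of the tested genes were called in the data. With BH adjustment, recovery and the share of false calls depend on how many genes change, so these values need not hold for the data.

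The model, the gene lists, the rule for naming genes and nearly all alternative settings were chosen before the data were examined. The named genes were Chchd2, Chchd10, Cox4i1, Cox4i2, Rbpj, Cxxc5, Trp53 and Dicer1 whatever their values, then the 12 genes with the greatest fitted rise and the 12 with the greatest fitted fall. Those 24 had to pass the test, reach 5 CPM in the higher genotype and show no overlap between genotypes, and unnamed gene models were passed over (1 among the rises and 0 among the falls). From each list, up to 4 called members of at least 1 CPM with the greatest change could be named. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

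There were 42 gene lists, with 1025 entries of which 1019 matched a gene in the table, 15 of them through a synonym. Lists with at least 5 tested genes were compared with the remaining genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with BH adjustment over 40 lists. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. Some genes belong to several lists. Members called with BH adjustment over all tested genes are given as the count, followed where it differs by the count adjusted over the list alone.

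The settings tried were scaling by DESeq2 size factors, by upper quartiles or by library totals, no filter and a filter of 1 CPM, DESeq2 1.42.0, limma voom, a non-robust fit, removal of mitochondrially encoded genes, the replicate number as a block, a threshold of 0.01, a test against a 1.5-fold change, and omission of each library in turn. After the data had been seen, 2 further settings were added, which left Chchd2 out of its list or left out the genes of chromosomes 5 and 13. No replicate pair agreed within sampling noise, since chi-square per degree of freedom was between 5.28 and 29.6 over the pairs of a genotype.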

Results

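Gene expression was measured by RNA sequencing in 3 libraries of MNRR1-knockout TKO ovarian cancer cells and 3 libraries of WT TKO cells. The comparison addressed how the transcriptome of this line differs once MNRR1, a protein of mitochondria and nucleus, is lost. Total counts were 33226463, 39969012 and 36723447 in KO replicates 1 to 3 and 36896199, 35328663 and 40983999 in WT replicates 1 to 3. Genes of mitochondrial DNA took 2.03% to 2.18% of the counts in KO libraries and 2.32% to 2.54% in WT libraries.

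Chchd2, the gene of MNRR1 (ENSMUSG00000070493, chromosome 5, positions 129881156 to 129887470 on the minus strand of GRCm38), was at 17.1 ± 0.499 CPM in KO libraries and 352 ± 13.7 CPM in WT libraries (SD, n = 3 each). The KO level was 4.85% of the WT level. Its counts were 581, 717 and 658 in KO replicates 1 to 3 and 12835, 11824 and 13506 in WT replicates 1 to 3, so the labels and the targeted gene went together in all 6 libraries. The log2 fold change was -4.37 (SE 0.06), with an adjusted p of 8.56e-12 in edgeR's quasi-likelihood test with BH adjustment. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The part of the gene that was altered is not given in the sources used here, and its processed pseudogene Chchd2-ps (chromosome 4, positions 148068031 to 148068492), examined after the results were seen, had counts of 34, 23 and 29 in KO and 15, 10 and 9 in WT libraries.

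Among gene lists, camera called matrix glycoprotein, matrix remodelling, mesenchymal and inflammatory genes lower in this KO clone, and ATF4 target, cholesterol synthesis and immediate early genes higher. None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.168, and collagen genes went both ways. Col1a1, a chain of type I collagen, fell from 134 ± 5.48 to 10.3 ± 1.85 CPM, and the chemokine gene Ccl2 fell from 204 ± 34.1 to 16.0 ± 6.41 CPM. The cystine transporter gene Slc7a11 rose from 5.76 ± 0.0818 to 32.2 ± 6.13 CPM, and the cell-cycle inhibitor gene Cdkn1a rose from 3.39 ± 0.157 to 18.8 ± 1.64 CPM (SD, n = 3 each). Of 16033 genes tested, 8925 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with BH adjustment, 4463 of them higher and 4462 lower in KO. At least a 2-fold change was seen for 1298 of the higher and 963 of the lower genes, and at least a 4-fold change for 288 and 368.

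The KO and WT values did not overlap for 64.0% of the tested genes, where chance gives 10% for 3 against 3. Correlations of log CPM across genes were at least 0.991 within KO, at least 0.993 within WT and between 0.952 and 0.970 across genotypes. The biological coefficient of variation was 8.35%. With scaling by library totals the median log2 change of all genes was 0.13, against 0.01 with TMM, and library totals gave 5771 higher and 3294 lower genes (63.7% higher), so small changes are relative to TMM scaling. KO replicate 2 lay nearer to WT than the other KO libraries did, and without it 10002 genes were called.

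**Figure D1:**
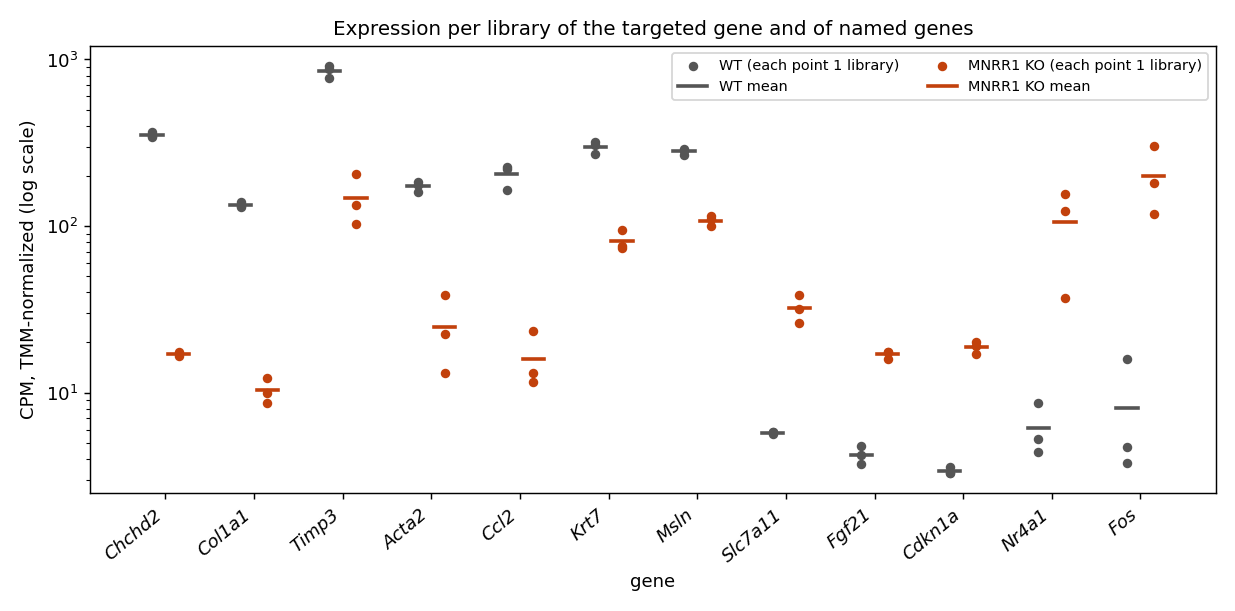
Expression of Chchd2 and 11 other genes named in the text, in TMM-scaled CPM on a log axis, with 1 point per library and a bar at the mean of each genotype. For Chchd2 the KO libraries sit at a mean of 17.1 CPM and the WT libraries at 352 CPM, and no gene shown has overlapping genotypes.

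The greatest rises were those of Fosb, Cyp26b1, Frzb, Fos, Ptpru, Nr4a1, Hoxa7, Egr2, Olfm1, Srcin1, Ypel3 and Ppp1r14a. Cyp26b1, which encodes an enzyme that degrades retinoic acid, rose from 0.772 ± 0.151 to 27.5 ± 1.05 CPM, a log2 change of 5.15 (SE 0.13). Frzb, which encodes a secreted Wnt antagonist, rose by 5.08 and the homeobox gene Hoxa7 by 4.02 on the log2 scale. Fosb and Fos, subunits of the AP-1 transcription factor, rose by 5.82 (SE 0.99) and 4.60 (SE 0.76), and varied widely between libraries. With the replicate number as a block in edgeR's quasi-likelihood test, both missed the threshold (adjusted p = 0.0695 and 0.0679). Fosb was at 187 ± 124 CPM in KO and 3.21 ± 3.25 CPM in WT libraries, and its log2 change was 5.16 without KO replicate 2 and 7.13 without WT replicate 3. Without WT replicate 3, Fos was at 5.56 and Egr2 at 4.92, against 3.92 for Egr2 with all libraries.

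The greatest falls were those of Peg10, Bex1, Gnai1, Zdbf2, Sgce, Gucy1a1, Hoxd8, Lin28b, Sulf1, Hdgfl3, Enpp3 and Ctsc. Peg10 and Bex1 had 0 counts in the 3 KO libraries and 2053 and 613 counts in the WT libraries. Against a floor of 3 counts over the KO group, Peg10 was at least 721-fold lower and Bex1 at least 215-fold lower. Gnai1, a G protein subunit gene, had 1 count in KO and 724 in WT libraries, a ratio of 763 (95% counting interval 137 to 30190). Sgce, the neighbour of Peg10 on chromosome 6, had 2 counts in KO and 760 in WT, a ratio of 401 (111 to 3314). Gucy1a1 had 3 counts in KO and 627 in WT, a ratio of 220 (75.1 to 1071). The single KO count of Gnai1 was in replicate 3, and its fitted log2 change moved from -9.11 to -10.94 without that library, as that of Gucy1a1 moved from -7.61 to -8.44. Lin28b, which encodes an inhibitor of let-7 microRNA processing, fell from 11.8 ± 1.74 to 0.0971 ± 0.0211 CPM, and the sulfatase gene Sulf1 fell from 28.1 ± 2.03 to 0.247 ± 0.0652 CPM.

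Among reported partners and targets of MNRR1, the Notch pathway transcription factor gene Rbpj fell by 0.56 on the log2 scale, with an adjusted p of 1.03e-05 in edgeR's quasi-likelihood test with BH adjustment. Cxxc5, a zinc finger gene reported to act with MNRR1 at promoters, rose by 0.51 (adjusted p = 7.34e-04). Chchd10, the closest relative of Chchd2, rose by 0.20 (adjusted p = 0.0216), and this call was lost without KO replicate 3, WT replicate 1, WT replicate 2 or WT replicate 3, at adjusted p of 0.0745, 0.0767, 0.0789 and 0.0568. The range of its adjusted p over all settings was 0.00228 to 0.0789. Cox4i1, the common isoform of a cytochrome c oxidase subunit, was at 305 ± 10.3 CPM in KO and 286 ± 7.15 CPM in WT libraries, a log2 change of 0.09 that missed the threshold (adjusted p = 0.141). It passed with scaling by library totals (adjusted p = 0.00194) or upper quartiles (0.0265), and its adjusted p ran from 0.00194 to 0.383 over the settings. Cox4i2 was below the filter, with counts of 10, 7 and 7 in KO and 2, 4 and 13 in WT libraries. The list of MNRR1 partners and reported targets had 9 tested genes, of which 2 rose and 5 fell, and was called lower by camera at an adjusted p of 1.27e-04, against an adjusted p of 0.168 with an estimated correlation. Chchd2 itself is a member, and without it the adjusted p was 0.563, while limma voom gave 0.199 for the list with Chchd2, in a range of 3.18e-07 to 0.563 over the settings.

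The labels do not name the genes knocked out in this line. Trp53, the gene of the tumour suppressor p53, fell by 0.16 on the log2 scale (adjusted p = 0.0165 in edgeR's quasi-likelihood test with BH adjustment). Dicer1, which encodes the enzyme that cuts microRNA precursors, was at 70.0 ± 4.96 CPM in KO and 71.3 ± 1.75 CPM in WT libraries (adjusted p = 0.756), and its log2 change of -0.02 turned to 0.10 with scaling by library totals, 0.03 with upper quartiles and 0.02 without KO replicate 2. The call of Trp53 was lost without KO replicate 1 (adjusted p = 0.0898), WT replicate 1 (0.0697) or WT replicate 2 (0.0580) and with scaling by library totals (0.453) or upper quartiles (0.0727), in a range of 5.83e-04 to 0.453.

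Camera called 20 of the 40 tested lists, 5 higher and 15 lower in KO. With an estimated correlation it called 0 of them, with a smallest adjusted p of 0.168 and 7 lists at an unadjusted p under 0.05. The muscle, stemness, TGF-beta, remodelling and immediate early lists had estimated correlations of -0.0650 to -0.00876, below the preset 0.01. These lists lost their calls as well, which argues against a higher correlation between genes as the reason for them. Fry, which does not compare a list with other genes, called 30 lists in 1 direction on balance and 40 when changes in either direction counted.

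**Figure D2:**
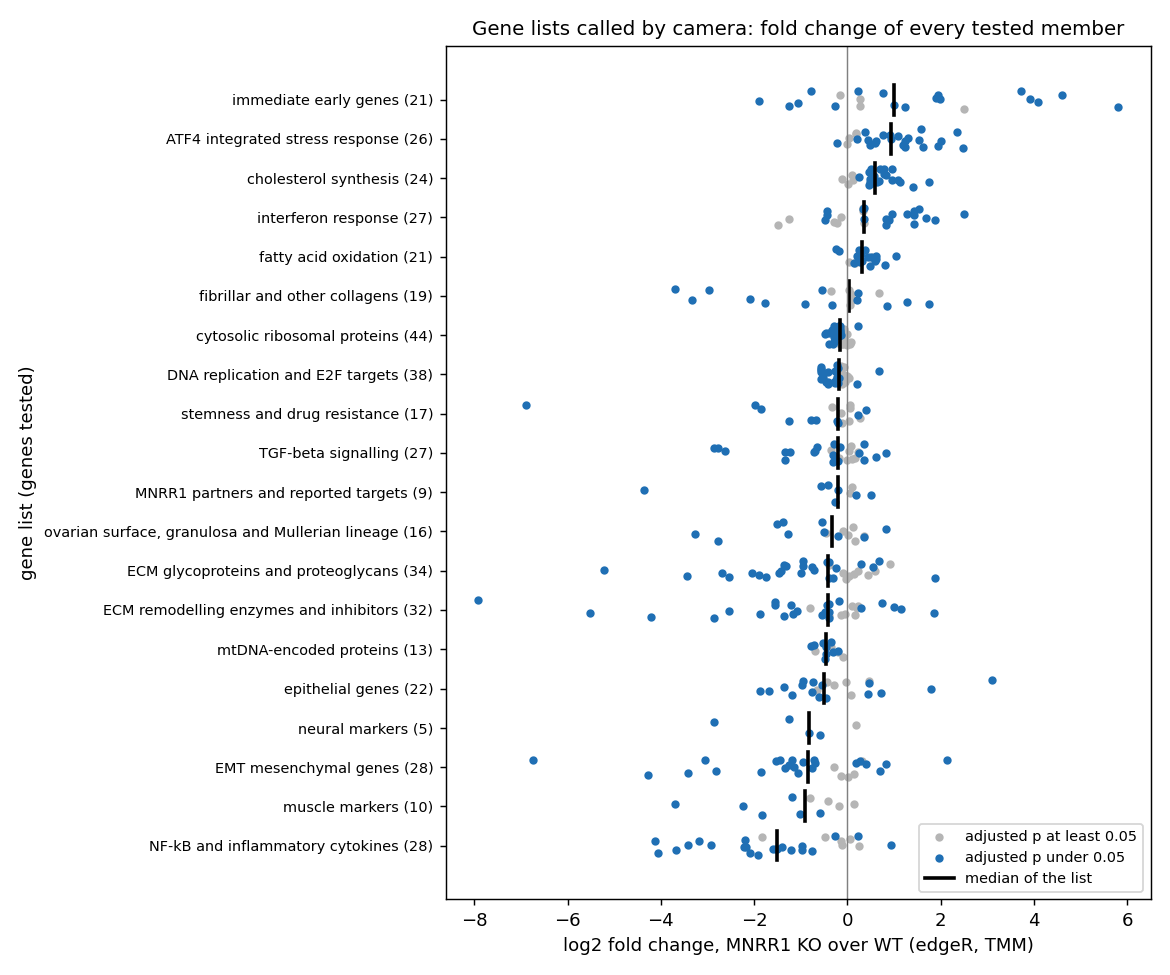
Log2 fold change of KO over WT for each tested gene of the 20 lists that camera called, with 1 point per gene, blue where the adjusted p was under 0.05 and grey elsewhere, and a black bar at the median of the list. Medians run from 1.01 for immediate early genes to -1.52 for NF-kB and inflammatory cytokines, and the median of collagens is at 0.04 although the list was called lower. Mmp16 of the remodelling list and Twist1 of the mesenchymal list had 0 counts in KO and are drawn at fitted values that are not bounds, and the medians of those lists stay at -0.42 and -0.85 with both genes at their bound. Mmp16 and Twist1 were chosen after their values were seen.

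Target genes of ATF4, the transcription factor of the integrated stress response, rose as a group. Of 26 tested genes, 21 rose and 1 fell, and the median log2 change was 0.93. Slc7a11 rose by 2.48, the cationic amino acid transporter gene Slc7a3 by 2.36, the hormone gene Fgf21 by 2.01 and Ddit4, an inhibitor of mTORC1 signalling, by 1.95 on the log2 scale. Camera gave an adjusted p of 3.88e-16, and the adjusted p was 0.168 with an estimated correlation. Atf4 itself, chosen after its value was seen, was at a log2 change of 0.03 and did not pass the test.

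Of 24 genes of cholesterol synthesis, 20 rose and 0 fell, with a median log2 change of 0.60. The pathway enzyme genes Tm7sf2, Mvd and Nsdhl rose by 1.40, 1.13 and 1.10. The camera adjusted p was 5.31e-11, against an adjusted p of 0.296 with an estimated correlation. Fatty acid oxidation genes also rose, 16 of 21 against 2 that fell, with Cpt1c at 1.04, Acaa2 at 0.80, Acadvl at 0.62 and Cpt2 at 0.62 (camera adjusted p = 0.00390, and adjusted p = 0.564 with an estimated correlation).

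Of 21 immediate early genes, which are induced within minutes of a stimulus, 12 rose and 5 fell, or 13 and 5 adjusted over the list alone, with a median log2 change of 1.01. Nr4a1, a nuclear receptor gene, rose by 4.09, beside Fosb, Fos and Egr2 above. The camera adjusted p was 0.00209, and the adjusted p was 0.168 with an estimated correlation. Of 27 interferon response genes, 15 rose and 3 fell, or 16 and 4 adjusted over the list alone, with Parp14 at 1.88, Rtp4 at 1.68 and Ifih1 at 1.54. Camera gave the interferon list an adjusted p of 0.0361, against an adjusted p of 0.739 with an estimated correlation. That call was lost without KO replicate 1 (adjusted p = 0.0720), KO replicate 3 (0.0755) or WT replicate 3 (0.126), and with library totals (0.101), upper quartiles (0.0550) or DESeq2 (0.0757), in a range of 0.00963 to 0.126.

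Inflammatory transcripts fell. Of 28 tested genes of the NF-kB and inflammatory cytokine list, 2 rose and 20 fell, or 2 and 23 adjusted over the list alone, with a median log2 change of -1.52. The chemokine genes Ccl7, Ccl2 and Ccl20 changed by -4.13, -3.67 and -3.42, and the adhesion molecule gene Icam1 by -4.06. Without KO replicate 2, Ccl7 was at -4.81. The camera adjusted p was 1.49e-09, against an adjusted p of 0.246 with an estimated correlation.

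Extracellular matrix genes were mostly lower. Of 34 glycoprotein and proteoglycan genes, 4 rose and 21 fell, with a median log2 change of -0.41. The basement membrane gene Nid1 was at -5.21, the fibrillin gene Fbn1 at -3.43, versican (Vcan) at -2.68 and Fbln5 at -2.54 (camera adjusted p = 4.71e-07, and adjusted p = 0.168 with an estimated correlation). Of 32 matrix remodelling genes, 5 rose and 19 fell, with a median of -0.42. They included the membrane-bound protease gene Mmp14 at -5.51 and Adam12 at -4.21, and also the protease inhibitor gene Timp3 at -2.53. Camera gave the remodelling list an adjusted p of 1.09e-04, against an adjusted p of 0.168 with an estimated correlation.

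Collagen genes went both ways. Of 19 tested, 5 rose and 8 fell, and the median log2 change was 0.04 while the mean was -0.56. Col1a1 was at -3.70, the basement membrane collagen genes Col4a1 and Col4a2 at -3.32 and -2.98, and Col5a2 at -2.08. Camera called the list lower (adjusted p = 0.0185, and adjusted p = 0.343 with an estimated correlation), and the call was lost without KO replicate 2 (adjusted p = 0.131) and in limma voom (0.424), in a range of 0.00114 to 0.424.

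Of 28 mesenchymal genes of the epithelial-mesenchymal transition, 6 rose and 17 fell, with a median log2 change of -0.85. The contractile genes Tagln, Cnn1, Myl9 and Acta2 were at -4.28, -3.42, -3.05 and -2.81, and Cnn1 was at -4.26 without KO replicate 2. The camera adjusted p was 3.67e-05, against an adjusted p of 0.246 with an estimated correlation. Epithelial genes fell in this clone as well, 11 of 22 against 5 that rose, with a median of -0.50 (camera adjusted p = 0.0120, and adjusted p = 0.246 with an estimated correlation). The keratin gene Krt7 was at -1.88 and the desmosome gene Dsg2 at -1.67, whereas the tight junction gene Tjp3 rose by 3.10 and the transcription factor gene Elf3 by 1.79.

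Of 16 genes of the ovarian surface, granulosa and Mullerian lineages, 2 rose and 8 fell. The activin subunit genes Inhba and Inhbb were at -2.77 and -1.27, the transcription factor gene Gata4 at -1.50 and mesothelin (Msln) at -1.38, and Inhba was at -3.67 without KO replicate 2. The camera adjusted p was 0.0126, against an adjusted p of 0.343 with an estimated correlation, and limma voom gave 0.0501, the highest of its settings, with 0.00459 the lowest. Of 27 TGF-beta signalling genes, 5 rose and 14 fell, with Ltbp2 at -2.63 and Eng at -1.33 (camera adjusted p = 0.0283, and adjusted p = 0.246 with an estimated correlation), and limma voom gave 0.0523 where the lowest of its settings was 0.00314. Of 17 stemness and drug resistance genes, 2 rose and 8 fell, among them Lin28b, Cd24a at -1.99, Cd44 at -1.84 and Aldh1a1 at -1.25. The stemness list had a camera adjusted p of 0.0189, an adjusted p of 0.246 with an estimated correlation and 0.0838 in limma voom, in a range of 0.00372 to 0.0838.

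Proteins encoded by mitochondrial DNA had lower transcripts, 9 of 13 lower and 0 higher, with a median log2 change of -0.45. The complex I genes mt-Nd6 and mt-Nd1 were at -0.52 and -0.48. The camera adjusted p was 0.0194, against an adjusted p of 0.597 with an estimated correlation. In WT libraries mt-Nd3 and mt-Co3 were at 25.5 and 14.3 CPM, far below mt-Nd1 at 4821 CPM, and the reason was not tested. The call of mt-Nd3 (-0.79) was lost without KO replicate 1, 2 or 3 and with no filter. That of mt-Co3 (-0.72) was lost without KO replicate 2 or 3. Of 22 nuclear genes on the list of complexes III and IV, 0 rose and 8 fell, and the list was not called (adjusted p = 0.256). Among them, Uqcrfs1 was at -0.55. Cycs (cytochrome c), on the list but a carrier between the complexes rather than a subunit, was at -0.70. Complex I genes (5 higher and 4 lower of 36, or 4 and 3 adjusted over the list alone, adjusted p = 0.775) and ATP synthase genes (3 and 2 of 14, or 3 and 1, adjusted p = 0.934) were not called. The same held for genes of the TCA cycle (7 higher and 4 lower of 20, or 7 and 5 adjusted over the list alone, adjusted p = 0.872), the mitochondrial unfolded protein response (7 and 5 of 15, adjusted p = 0.718) and mitochondrial biogenesis and dynamics (4 and 11 of 24, adjusted p = 0.361). Chchd4, an import protein gene of the biogenesis list, was at -0.95. With scaling by library totals the medians of complexes III and IV, of ATP synthase, TCA cycle, biogenesis and mitosis genes turned from -0.07, -0.05, -0.01, -0.03 and -0.11 to 0.05, 0.07, 0.11, 0.09 and 0.01.

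Cytosolic ribosomal protein genes were slightly lower, 24 of 44 against 1 higher, or 26 and 1 adjusted over the list alone, with a median log2 change of -0.15. Camera gave an adjusted p of 0.0194, against an adjusted p of 0.781 with an estimated correlation. The ribosomal call was lost without KO replicate 3 (adjusted p = 0.0505) and with library totals (0.140), in a range of 5.10e-04 to 0.140. Of 38 DNA replication and E2F target genes, 2 rose and 19 fell, with a median of -0.19, and E2f2, Rrm1, E2f1 and Tyms were at 0.68, -0.57, -0.57 and -0.56. The replication list had a camera adjusted p of 0.0120, an adjusted p of 0.643 with an estimated correlation and 0.0542 with library totals, in a range of 3.73e-04 to 0.0542. Mitosis genes (7 higher and 15 lower of 36, adjusted p = 0.275) and histone genes (1 and 1 of 15, or 1 and 0 adjusted over the list alone, adjusted p = 0.707) were not called.

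p53 target genes moved in both directions, 9 higher and 10 lower of 23, with a median log2 change of -0.15 and a mean of 0.22. Trp53inp1 rose by 2.77, Cdkn1a by 2.47 and Btg2 by 1.93, and Plk2 was at -2.51 (camera adjusted p = 0.107). Among 28 apoptosis regulators, 12 rose and 8 fell, with the pro-apoptotic genes Bmf and Bik at 3.07 and 3.06 (adjusted p = 0.283). Notch pathway genes moved in both directions, 5 higher and 5 lower of 18 (adjusted p = 0.486), with the receptor genes Notch3 and Notch1 at 3.32 and 2.34, the ligand gene Jag1 at -2.01 and the glycosyltransferase gene Lfng at -2.26. Of 23 Wnt pathway genes, 5 rose and 15 fell, with Axin2 at -2.10, Lef1 at 1.70 and Ccnd1 at -1.27. The Wnt antagonist gene Sfrp1 had 2 counts in KO and 258 in WT libraries, a ratio of 136 (95% counting interval 37.3 to 1129). The Wnt list was not called (adjusted p = 0.112) but passed without WT replicate 1 (adjusted p = 0.0474, the lowest of its settings, with 0.348 the highest). Integrin genes, 2 higher and 8 lower of 13, or 2 and 9 adjusted over the list alone, were not called either (adjusted p = 0.0577) and passed without WT replicate 3 (adjusted p = 0.0447, the lowest of its settings, with 0.160 the highest).

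Hypoxia response genes (10 higher and 9 lower of 25, adjusted p = 0.868) and glycolysis genes (8 and 7 of 22, adjusted p = 0.872) were not called, although Car9 rose by 2.07, Aldoc rose by 2.20 and Slc2a3 was at -1.67. Antioxidant and NRF2 target genes (10 and 7 of 24, adjusted p = 0.486) included Gsta4 at 2.10 and Gpx1 at -0.67. Angiogenesis factors (6 and 8 of 22, or 7 and 8 adjusted over the list alone, adjusted p = 0.348) included Pgf at 1.96 and Nrp1 at -1.70. In the MHC class I and antigen processing list (6 and 3 of 15, adjusted p = 0.577) the peptide transporter gene Tap2 rose by 1.88, and H2-K1 was at -0.73.

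Camera called the muscle and neural markers lower in KO. Of 10 tested muscle markers, 6 fell and 0 rose, with the smooth muscle actin gene Actg2 at -3.70 (camera adjusted p = 0.0120, and adjusted p = 0.246 with an estimated correlation), a call lost without KO replicate 2 (adjusted p = 0.0659, the highest of its settings, with 0.00562 the lowest). Of 5 tested neural markers, 4 fell and 0 rose, with Tubb3 at -1.24 and Map2 at -0.83 (camera adjusted p = 0.00840, and adjusted p = 0.254 with an estimated correlation). The neural call was lost with no filter (adjusted p = 0.143) and in DESeq2 (0.103), with 0.00602 the lowest of its settings. The neural median of -0.83 turned to 0.19 with no filter and was -0.06 in DESeq2. Leukocyte markers (0 higher and 3 lower of 5, adjusted p = 0.275) and endothelial markers (2 and 2 of 7, or 3 and 2 adjusted over the list alone, adjusted p = 0.872) were not called. The median and camera's direction differed in sign for collagens, which were called, and for p53 target, Notch, hypoxia, endothelial and TCA cycle genes, which were not. Of the erythroid markers, 3 were tested, too few for camera, and Epb42 rose by 3.14.

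The fold changes were not spread evenly over the genome. Genes of chromosome 13 had a median log2 change of -0.28 (95% bootstrap interval -0.33 to -0.24), with 266 lower and 73 higher of 546 tested. Chromosome 5 was at -0.15 and chromosome 14 at -0.09, while chromosomes 7 and 18 were at 0.15 each. Against random gene sets of equal size, each of these 5 chromosomes had an adjusted p of 0.002. All 5 shared the smallest unadjusted p obtained, 5.00e-04, so these p-values do not rank them. Random sets treat genes as independent, and the genes come from 1 clone. Chromosomes 8 and 6, at 0.08 and 0.06, had adjusted p of 0.00666 and 0.0228. With scaling by library totals the medians were -0.16 on chromosome 13, -0.03 on chromosome 5, 0.03 on chromosome 14 and 0.27 on chromosomes 7 and 18. Of the genes named above, Uqcrfs1, Nid1, Vcan, Inhba and Plk2 lie on chromosome 13, Chchd2, Rbpj, Tyms, Gnai1 and Lfng on chromosome 5, Mmp14 and Gata4 on chromosome 14, and Cxxc5, Acaa2 and Dsg2 on chromosome 18. Chromosome 7 holds Fosb, Ypel3, Ppp1r14a, Hdgfl3, Ctsc, Fgf21, Rrm1, Adam12, Cpt1c and Ccnd1.

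**Figure D3:**
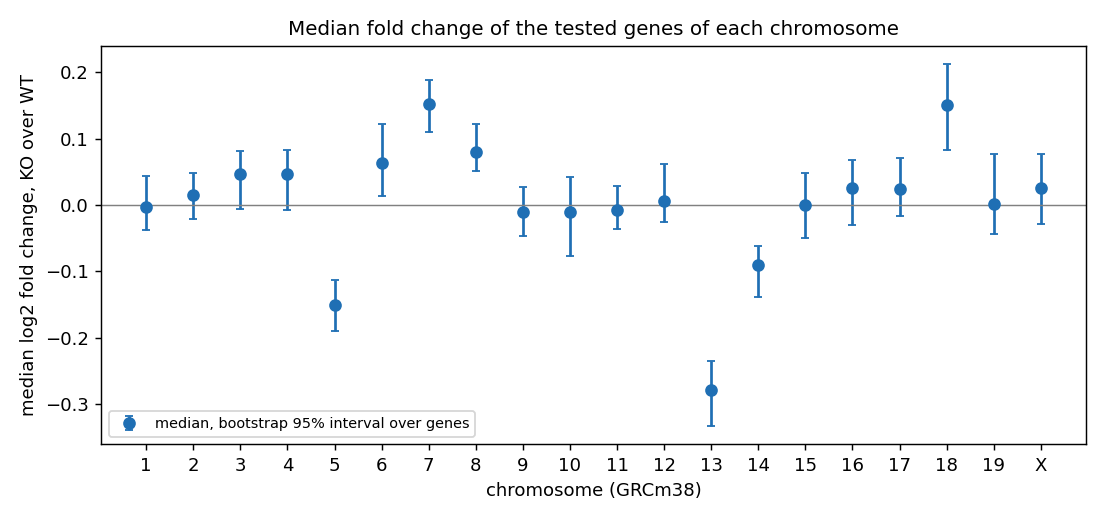
Median log2 fold change of KO over WT for the tested genes of each chromosome, with bars for the 95% bootstrap interval over genes. Chromosome 13 is the lowest at -0.28, and chromosomes 7 and 18 are the highest at 0.15.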

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

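Of 174 named genes besides Chchd2, 161 kept their direction and their side of the threshold in all settings run on them, and 13 changed call or direction in some setting. Most of these genes were named because they passed the test with large changes in the same fit, which favours keeping the call. Of all genes called in the main fit, 83.3% to 97.1% were also called when a library was left out, and 86.9% with library totals. Chchd2 stayed lower in all settings. Genes past the threshold numbered 8232 to 9305 across scalings, filters and tools, 6887 at a threshold of 0.01, and 7587 to 10002 when a library was left out, against 8925. Genes with at least a 2-fold change numbered 1542 with the 1 CPM filter, 2802 with no filter and 2076 to 2749 when a library was left out, against 2261. With library totals 65.8% of the genes with at least a 2-fold change were higher. The test against a 1.5-fold change, which sets no 2-fold limit, called 2277 genes. Leaving out chromosomes 5 and 13, a choice made after seeing the data, left 7981 and 2053 genes. Lists called by camera numbered 15 in limma voom to 20, and 18 to 21 when a library was left out, but 0 with an estimated correlation (fry called 30). Lists with an estimated correlation below the preset 0.01 lost their calls too. A higher correlation between genes alone therefore does not account for the loss, and its cause was not tested further.

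Dicer1 turned to 0.0968 with library totals, 0.0267 with upper quartiles and 0.0226 without KO replicate 2 (-0.0788 to 0.0226 over omitted libraries). Camera's direction, not called in any of these, turned for ATP synthase genes (medians 0.0678 with library totals, -0.000837 with upper quartiles, -0.0445 with the 1 CPM filter, -0.0320 without KO replicate 1 and -0.0386 without KO replicate 3, in a range of -0.0736 to -0.0320 over omitted libraries), glycolysis (0.0839 with no filter), endothelial markers (0.274 in limma voom and 0.318 without KO replicate 2, in a range of 0.129 to 0.403), the mitochondrial unfolded protein response (0.114 without KO replicate 2, in a range of 0.114 to 0.145) and the TCA cycle (-0.0303 without KO replicate 2, in a range of -0.0303 to 0.00344). The cause was not tested.

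Samples with the same number did not deviate together (correlations across genes -0.06, 0.05 and 0.03). The descriptions give the numbers as sets without saying what a set shares. With 3 libraries per genotype these correlations cannot exclude a pairing, which stays open. With the replicate block 8878 genes, 2259 genes with at least a 2-fold change and 20 lists were called, Chchd2 was at -4.37, and Fosb (5.64, adjusted p = 0.0695) and Fos (4.63, adjusted p = 0.0679) missed the threshold, each at the highest adjusted p of its settings, the lowest being 3.81e-09 and 3.08e-09. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 8925 genes, 2261 genes with at least a 2-fold change and 20 lists, and the highest of the others gave 0, 0 and 14, so 1 split was as large in each case. Each other split mixes the genotypes, so the genotype difference adds to its spread and its 0 called genes carry little information. Camera still called 5 to 14 lists in these mixed splits. In the simulation, where 200 genes were changed, changes of 1.2-fold and 1.5-fold were recovered for 24% and 64% of genes. These rates need not hold for the data, where far more genes were called.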

Other observations

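The gene groups of this part and the tests on wild-type RNA, the pseudogene Chchd2-ps and imprinted genes were chosen after the results had been seen. Of 20 tested homeobox genes of the Hox clusters, 10 were higher and 4 lower in KO in edgeR's quasi-likelihood test with BH adjustment, where 55.7% of all tested genes were called, and whether Hox genes changed more often than others was not tested. Hoxa4, Hoxa5, Hoxa6 and Hoxa7, neighbours on chromosome 6, rose by 2.54, 1.71, 3.18 and 4.02 on the log2 scale. Hoxb9 rose by 1.46, and Hoxc4, Hoxc6, Hoxc8, Hoxc9 and Hoxc10 rose by 0.51 to 0.97. Hoxd8, Hoxd4, Hoxd3 and Hoxc11 were at -7.37, -3.32, -1.19 and -2.08.

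Peg10, Sgce and Zdbf2, among the greatest falls, are imprinted genes, which are expressed from the copy of a single parent, and this led to a hypothesis that imprinted genes differ more often than others in this clone. On a list of 49 imprinted genes drawn up after those falls had been seen, 37 were tested and 15 changed at least 2-fold (11 lower and 4 higher), or 40.5% against 14.0% of other genes, with a one-sided Fisher's exact p of 7.18e-05. Peg10, Sgce, Zdbf2 and Slc38a4 had already been seen, and leaving out these 4 was decided after that p was known. Of the remaining 33 genes, 11 changed at least 2-fold (33.3%, one-sided Fisher's exact p = 0.00412, odds ratio 3.06). These 11 still include Ppp1r9a (-4.29), on chromosome 6 like Peg10 and Sgce, and the list followed the falls that prompted it. The p without the 4 genes is therefore not an independent test. The neighbours Rtl1, Rian and Mirg on chromosome 12 rose by 2.36, 2.89 and 2.88, and Mest, Plagl1 and Impact were at -2.01, -1.88 and -1.37. Rtl1 rose from 1.60 to 8.27 CPM. Rian and Mirg rose from 0.0848 to 0.641 CPM and from 0.0738 to 0.568 CPM. Their WT levels were near the floor of a single library, so the sizes of these 2 rises are uncertain (SE 0.50 and 0.48). Imprinted genes lie in clusters and are not independent, so the p-values may be too small, and with 1 clone a change of imprinting during cloning cannot be separated from an effect of MNRR1 loss.

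Genes of chromosome 13 were lower in KO, by -0.28 at the median. A trend with GC content, gene length or expression level is argued against, since removing such trends left a median of -0.283 (95% interval -0.325 to -0.230). A candidate explanation is fewer copies of chromosome 13 in the KO clone, which would lower the whole distribution. The 75th percentile lay -0.299 from that of other autosomes (95% interval -0.380 to -0.239). An effect of MNRR1 loss itself stays open, because the series holds 1 KO clone.

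KO replicate 2 lay nearer to WT, with a slope of its deviation on the genotype difference of -0.212, against 0.0114 and 0.0792 in KO replicates 1 and 3. WT replicate 3 lay nearer to KO at 0.105, against 0.0196 and 0.00989 in WT replicates 1 and 2. Simulated slopes ran from -0.0512 to -0.0350 over the KO libraries and from 0.0354 to 0.0567 over the WT libraries. All 6 slopes lay outside their simulated ranges. KO replicate 2 and WT replicate 3 lay past theirs toward the other genotype, and the other libraries lay past theirs away from it. Wild-type RNA in KO replicate 2 is argued against by 16 genes nearly lost in the other KO libraries. In KO replicate 2 these genes were at 1.27% of the WT level (exact Poisson 95% interval 1.05% to 1.52%), and at 1.06% in the other KO libraries. Sequencing depth is argued against by a slope of -0.215 after all libraries were thinned to the smallest total. A trend with GC content or gene length is argued against by a slope of -0.210 once it was removed. A difference in culture state between the KO samples may remain, and no biological explanation was tested.

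Chchd2 counts remained in the KO libraries at 4.85% of the WT level. Wild-type cells or RNA in the KO cultures are argued against, because 17 of 10026 genes lay below the level that such a share would give (Poisson test with Bonferroni correction). Peg10, for example, would have 105 counts at that share and had 0. The pseudogene Chchd2-ps had a count of its own that was 4.40% of the remaining Chchd2 count. Pseudogene reads assigned to Chchd2 are not part of that count, so it cannot decide whether such reads are a source. Transcripts of the edited gene may remain, which gene counts cannot show.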
